A study of Mus musculus with 12 samples.

How the data were processed

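Gene expression was measured on 1-colour arrays in ovaries of 12 female mice, 1 array per ovary sample, at 23 weeks of age and at diestrus, the resting phase of the estrous cycle, as staged by vaginal smear. Per the labels' protocols, RNA was extracted with Trizol, purified on columns and labelled with biotin. The labels' protocol for labelling also names Cy3 and Cy5 dyes, and the values hold 1 channel per sample. The probe sets are those of the Affymetrix mouse expression array that the platform annotation describes.

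The values that the authors deposited are on a log2 scale, 1 per probe set and array. The summary method and the normalization that made them are not given in the sources used here. The scale was settled from the values, which run from 2.69 to 14.4. A natural log of a 16-bit scanner value ends at 11.1, and a log2 ends at 16. Array medians lay between 7.09 and 7.15, the upper quartiles differed by at most 0.055 and the lower quartiles by at most 0.16, so the arrays had been brought to nearly 1 distribution before deposit. A change in the total amount of RNA per cell cannot be seen in such values. Detection calls and scanner intensities were not used here, so no probe set has a measured background limit.

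The table used here holds 16376 probe sets, which are only the lower part of the array's range of probe set names. Genes measured by other probe sets were not analysed here. The platform annotation paired 14674 probe sets with 1 gene symbol, 427 with several and 1275 with none. Of the first kind, 14632 had their Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table served for symbols and for the order of genes along chromosomes, and no coordinates are printed. Probe sets with several symbols or none were left out of the main comparisons. A gene with more than 1 probe set, which held for 2854 genes, was represented by the probe set with the highest mean over all 12 arrays, and this left 10949 genes.

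The groups follow the genotype and the tumor progression stage in the labels. There were 6 control arrays (Pgrcre/+, no tumor), 3 arrays of stage I and 3 arrays of stage II, both with the PgrBLsL allele besides Pgrcre. One linear model with a mean for each of the 3 groups was fitted to all arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the groups shared 1 estimate of the spread per gene, with 9 residual and 3.13 prior degrees of freedom. The 4 comparisons were the mean of both stages against control, stage I against control, stage II against control, and stage II against stage I. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and 0.05 was the threshold for the adjusted p. Fold changes are differences of log2 means, with the standard error (SE) of the model, and group values are means with their standard deviation (SD).

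Before the data were examined, 24 lists of cell type markers and pathway genes were fixed, with 350 entries, of which 226 were measured. Each list was tested in each comparison with limma's camera at its preset correlation of 0.01 between genes, and the 96 tests were adjusted together. Counts of list members past the threshold are given over all genes and adjusted over the list alone. The tests were repeated with the correlation estimated from the residuals. With the preset correlation 31 of the 96 tests passed, and with an estimated correlation 0 of 96 passed. A list score is the mean over the members of an array's deviation from the control mean.

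The rule for genes named in the text was also fixed before the data were examined. Pgr came first. For each comparison it took the 8 highest and the 8 lowest log2 fold changes among genes past the threshold whose groups of arrays did not overlap, without predicted genes and clone symbols. From each list it took up to 4 members past the threshold with the largest absolute change, or up to 2 members with the largest absolute change where none passed, given as values. The text names only part of the genes that the rule took. Calls of some genes left unnamed also ended without single arrays. Other genes were named only where the text says that they were chosen after their values were seen.

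The alternatives tried were quantile normalization, centring of array medians, a filter on the dimmest 25 percent of genes, the mean of a gene's probe sets, a test of every probe set, fits of the compared groups alone, array weights, a trended and robust variance prior, the replicate number as a block, each array left out in turn, and a floor of 2-fold. After the data were seen, control replicates 1 and 4 were left out together, and so were the 3 arrays with the highest Ovgp1, an oviduct marker. Because both stages were set against the same controls, their overlap was set beside 100 simulated unchanged groups and 20 splits of the controls into 3 and 3.

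The scripts were tested on simulated data with 200 changed genes among 10949. At a log2 change of 1, stage I against control recovered 96 percent of the changed genes, stage II against control and stage II against stage I each recovered 94 percent, and the genotype comparison recovered 98 percent. At a log2 change of 0.5 the shares were 70, 70, 56 and 84 percent in that order. False calls made up 6.63, 5.21, 3.85 and 2.55 percent of the calls. The simulated noise was independent, with 1 SD per gene in all groups. Real spreads differed between groups in some genes, such as Prl7a2 with an SD of 0.2 in controls and 1.29 in stage I. Recovery in the real arrays may therefore be lower. Zbtb16, for example, differed by 1.1 in stage I without passing (limma, adjusted p = 0.53). The precision is limited by the number of arrays. The labels call the samples biological replicates, so p-values measure the spread between such samples. Batch, hybridisation date and litter of each sample are not given in the sources used here.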

Results

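Ovaries were profiled on expression arrays in 12 mice of 23 weeks at diestrus. The 6 control mice carried Pgrcre/+ alone and had no tumor per the labels. The other 6 carried a PgrBLsL allele besides Pgrcre and fell into 3 ovaries of tumor stage I and 3 of stage II. Pgr encodes the progesterone receptor, and the series title names constitutive expression of its isoforms and ovarian neoplasia as the subject. The comparisons ask how expression in the ovary differed with the PgrBLsL genotype and between its tumor stages. Every ovary with the allele had a tumor stage, and no control had a tumor. Effects of allele and tumor therefore cannot be told apart in comparisons with controls. Correlations between arrays over all genes ran from 0.967 to 0.9969, and 0 pairs of arrays were identical. The first principal component held 55.2% of the variance, with controls between -17.6 and -15.1, stage I at 9.9, -4.6 and -6.5, and stage II at 30.2, 27.6 and 42.2. Control replicates 1 and 4 stood apart on the second component (17.4 and 19.4).

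**Figure D1:**
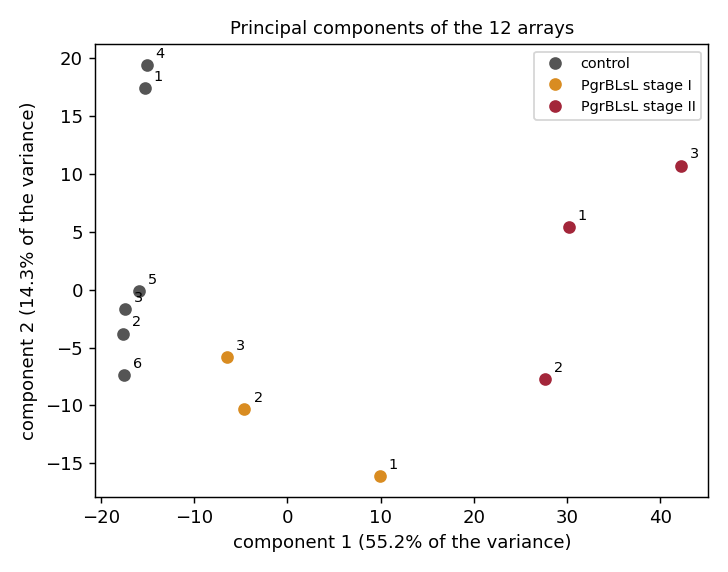
Scores of the 12 arrays on the first component (horizontal, 55.2% of the variance) and the second (vertical, 14.3%), each point an array with its replicate number and coloured by group. All 3 stage II arrays lie above 27 on the first component and all 6 controls lie below -15, with the 3 stage I arrays between them.

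Pgr, the gene the PgrBLsL allele is named for, was measured by 1 probe set and separated the genotypes on every array. Its log2 level was 4.20 ± 0.28 (SD, n = 6) in controls, 9.15 ± 0.12 (n = 3) in stage I and 9.94 ± 0.16 (n = 3) in stage II. Single arrays lay between 3.74 and 4.60 in controls, between 9.05 and 9.28 in stage I and between 9.78 and 10.09 in stage II. Pgr was 30.9-fold higher in stage I than in controls (limma, adjusted p = 2.4e-09) and 53.7-fold higher in stage II (adjusted p = 4e-10). Stage II exceeded stage I by 1.74-fold (log2 0.80 ± 0.17 SE, adjusted p = 0.012), a call that ended without stage II replicate 3 (adjusted p = 0.051). Which Pgr transcripts the probe set reads was not analysed here.

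**Figure D2:**
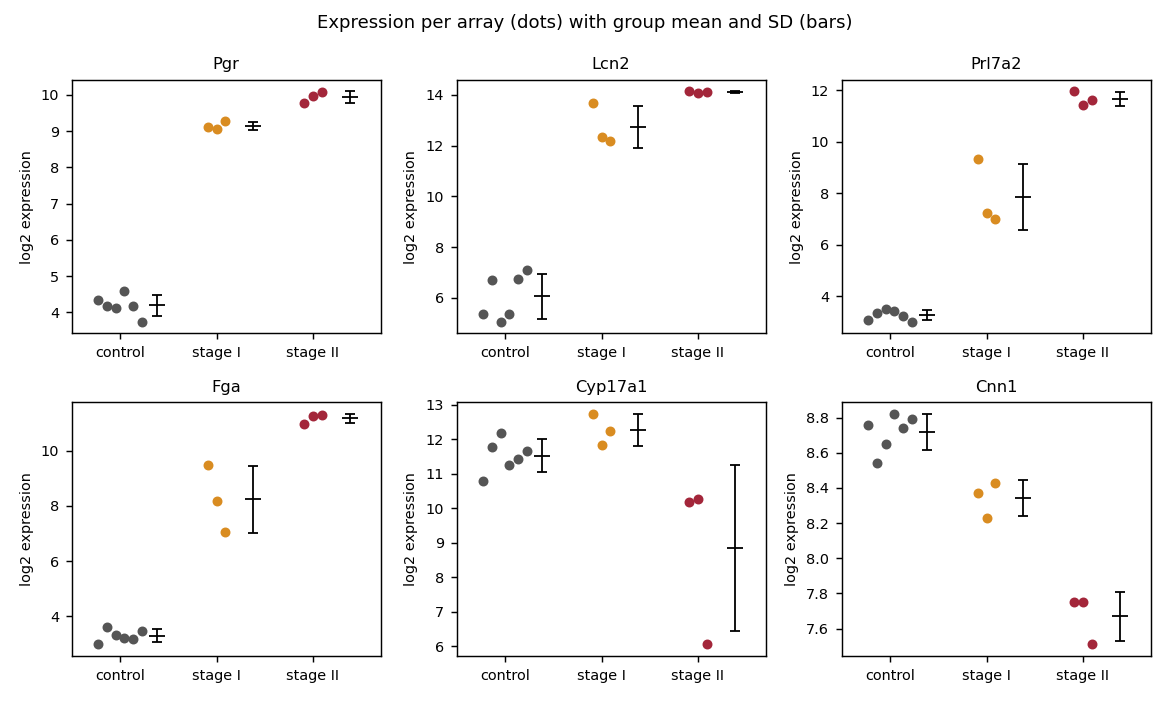
Log2 expression (vertical, a separate range in each panel that does not start at 0) of 6 genes in the 3 groups (horizontal), each dot an array, with the group mean and SD as bars beside it. Pgr, Lcn2, Prl7a2 and Fga separate all controls from all arrays of both stages, while Cyp17a1 in stage II runs from 6.06 to 10.26.

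The genotype comparison set the mean of both stages against the controls. Among called genes whose groups did not overlap, predicted genes and clone symbols left out, the largest increases were in Lcn2, a siderophore-binding secreted protein of innate immunity, at 164-fold (log2 7.36 ± 0.39 SE), and Prl7a2, a prolactin-family gene of the placenta, at 90.8-fold (log2 6.51 ± 0.32 SE). Fga, the fibrinogen alpha chain made by liver, rose 84-fold, and Svs5, a seminal vesicle secretory protein, rose 73-fold. The beta-defensin gene Defb8 rose 61.2-fold, Pmaip1, which encodes the pro-apoptotic protein Noxa, rose 33.8-fold, and Ly6d, a lipid-anchored surface antigen, rose 30.4-fold. Decreases among such genes were smaller, led by Cited4, a transcriptional co-activator (log2 -0.94 ± 0.23 SE), Emb, the adhesion protein embigin (-0.93 ± 0.21 SE), and the smooth muscle genes Cnn1 (-0.71 ± 0.07 SE) and Actg2 (-0.66 ± 0.07 SE). In each of these genes every array of the 6 with the allele lay on the same side of all 6 controls. Control levels of Prl7a2 (3.00 to 3.51) and Fga (2.99 to 3.63) lay near the lowest value in the table, 2.69, and Lcn2 in stage II (14.08 to 14.14) lay near the highest, 14.4. Other genes named here also started low, such as Pgr (3.74 to 4.60), Lrp2 (3.63 to 4.19) and Hand2 (4.05 to 4.39) in controls and Ugt2b34 in stage I replicates 2 and 3 (4.09 and 4.21). Background was not measured, so the folds of all such genes are ratios of deposited values and may differ from ratios of transcripts.

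Of 10949 genes tested, 740 passed limma's threshold in this comparison, 520 higher and 220 lower, and 138 of them differed by at least 2-fold. After quantile normalization the split was 504 higher and 345 lower. The smooth muscle and pericyte list held 6 members that fell and 0 that rose of 10 measured, with 7 lower when adjusted over the list alone (camera, adjusted p = 6.8e-06). Its adjusted p was 0.42 with an estimated correlation. Of 9 macrophage markers 5 rose and 0 fell (6 adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.44 with an estimated correlation), among them Cd14, a co-receptor for bacterial lipopolysaccharide (3.21-fold), and Csf1r, the receptor for macrophage colony-stimulating factor (1.39-fold). All 11 oocyte markers were lower in value and 2 of them fell, among them Nlrp5, a maternal-effect gene (log2 -0.53), while 11 were lower when adjusted over the list alone (adjusted p = 5.3e-06, and adjusted p = 0.49 with an estimated correlation). In stage I alone the oocyte list had a median of -0.06 with 0 passing (adjusted p = 0.29), against -0.76 in stage II. The other oocyte call, H1f8, ended without any single array except control replicate 1 or stage II replicate 2 (adjusted p up to 0.099). The C1qa call among the macrophage markers ended without any of control replicates 1 to 4. That call also ended without stage I replicates 1 or 3, or stage II replicates 1 or 3 (adjusted p up to 0.087 in these fits).

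The p53 target list held 3 risen members of 8, Pmaip1, Mdm2 (1.72-fold), which encodes the ubiquitin ligase of p53, and Ccng1 (1.48-fold), which encodes cyclin G1. The count was also 3 when adjusted over the list alone (adjusted p = 0.0079, and adjusted p = 0.43 with an estimated correlation). The median of the p53 list was 0.12, and it ran from 0.04 to 0.23 with each array left out in turn. Fibroblast and matrix genes went both ways, with 2 risen, Fn1 (fibronectin, 4.94-fold) and Mmp2 (a gelatinase, 1.41-fold), and 5 fallen of 14, such as Thy1 and Col5a1 (both log2 -0.39). That list had a median of -0.22, a mean of 0.02 and a lower direction by its test, with 2 higher and 7 lower adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.43 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 4-fold as the 1 called member of 17 proliferation genes, also 1 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.69 with an estimated correlation). Among 5 interferon response genes Usp18, a protease acting on ISG15, rose 1.81-fold and 4 rose adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation). In stage I alone the fibroblast, proliferation and interferon lists did not pass (medians -0.01, 0.03 and 0.27, adjusted p = 0.98, 0.35 and 0.16).

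The count of 740 became 42 when 2 groups of 6 arrays were fitted with 1 mean each, and 1321 with array weights. The fibroblast call ended without control replicate 6, stage I replicate 1, stage I replicate 2 or stage II replicate 3 (adjusted p up to 0.12), with quantile normalization (0.067) and without the dimmest genes (0.070), the proliferation call without control replicate 1, control replicate 5 or stage II replicate 3 (up to 0.093), and the interferon call without stage II replicate 1 (0.067). Without control replicates 1 and 4 together the proliferation and interferon lists did not pass either (0.15 and 0.073). With the replicate number as a block the proliferation list did not pass (0.11). The Usp18 call ended without control replicates 1, 2, 4 or 5, any stage I array, or stage II replicates 1 or 3 (up to 0.11), and with the mean of its probe sets (0.051). The Cited4 call ended without any of control replicates 1, 4, 5 and 6 and stage II replicates 1 and 2 (adjusted p up to 0.061).

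Stage I against control gave 21 genes, all higher and all by at least 2-fold. Lcn2 was 102-fold higher (log2 6.68 ± 0.48 SE, adjusted p = 4e-05), Svs5 was 43.7-fold higher (5.45 ± 0.51 SE, adjusted p = 0.00029), and Fga was 30.4-fold higher (4.93 ± 0.37 SE, adjusted p = 4.6e-05). Prl7a2 rose 24.2-fold, Defb8 rose 20.4-fold, Pmaip1 rose 14.8-fold, and Tspan8, a tetraspanin of epithelia, rose 14.4-fold. Ccnd1 and Fn1 were the other list members among them. Ccnd1, which encodes cyclin D1 and is a Wnt target, rose 4.85-fold (adjusted p = 0.0054), and Fn1 rose 3.05-fold (adjusted p = 0.015). Limma called 0 genes lower, while 284 genes were lower and 414 higher at an unadjusted p under 0.05. Quantile normalization gave 1 lower call, as did array weights and the replicate block. The fits without control replicate 4 and without stage I replicate 2 also gave 1 each.

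Among the 3 stage I arrays, replicate 1 carried the highest value of each of these genes except Pgr. Without it the log2 change was 4.68 for Svs5, 4.31 for Fga, 3.86 for Prl7a2, 3.50 for Defb8, 3.25 for Pmaip1 and 3.24 for Tspan8, and each still passed. Fga was at 5.52 without stage I replicate 3. The SD in stage I exceeded that in controls in Fga (1.21 against 0.23) and Svs5 (1.37 against 0.62). It did not in Lcn2 (0.84 against 0.90) or Pgr (0.12 against 0.28). Where stage I spread more, the spread shared by all groups may understate its SE and p-values. The count of genes was 13 without control replicates 1 and 4 and 11 without the 3 arrays with the highest Ovgp1.

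By lists, the cholesterol synthesis genes were lower as a group in stage I, with a median log2 change of -0.52 and all 12 members below 0 (adjusted p = 1.4e-06). Its scores in stage I replicates 1, 2 and 3 were -0.83, -0.41 and -0.40. Only replicate 1 lay clearly below the lowest control score, -0.41 in control replicate 3. Without control replicates 1 and 4, where the scores of this list were high, the median was -0.35 (adjusted p = 0.0026). With all arrays the adjusted p was 0.48 with an estimated correlation, and 0 members passed, over all genes or adjusted over the list alone. Fdps, a farnesyl diphosphate synthase, had a log2 difference of -0.99 (adjusted p = 0.77), and Lss, lanosterol synthase, had -0.87 (adjusted p = 0.76). All 9 macrophage markers were above 0 with a median of 0.44, 0 passing over all genes and 5 adjusted over the list alone (adjusted p = 3.6e-07, and adjusted p = 0.43 with an estimated correlation). The macrophage score differed between the stage I arrays, at 0.85, 0 and 0.42 in replicates 1, 2 and 3, and without replicate 1 the median was 0.26 (adjusted p = 0.003). All 10 smooth muscle and pericyte markers were below 0 with a median of -0.20, 0 passing and 2 lower adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.42 with an estimated correlation).

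Luteal cell markers had a median of -0.97 in stage I, with 0 of 7 passing and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.038, and adjusted p = 0.64 with an estimated correlation). Their scores were high in control replicates 1 and 4 (0.79 and 0.94) against -0.63 to -0.07 in the other controls, as were the cholesterol scores (0.44 and 0.55 against -0.41 to -0.03). Without these controls the luteal median was -0.62 with an adjusted p of 0.51. Leaving out control replicate 1, control replicate 4, stage I replicate 1, stage I replicate 2 or stage II replicate 3 alone also ended the luteal call, with a median of -0.31 and an adjusted p of 0.43 without stage I replicate 1. The call also ended without the 3 arrays with the highest Ovgp1 (0.063), with quantile normalization (0.065), without the dimmest genes (0.057) and with the replicate block (0.11). The p53 list passed in stage I, where Pmaip1 was the 1 called member of 8, also 1 adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.44 with an estimated correlation). Its median was 0.04 and its mean 0.52, with 5 members above 0 and 3 below. Immediate early genes, which respond within minutes to stimuli and to tissue handling, had a median of -0.49, with 0 of 9 passing and 1 higher adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.64 with an estimated correlation). The p53 call ended without control replicate 4, stage I replicate 2 or stage I replicate 3 (adjusted p up to 0.16), and without control replicates 1 and 4 together (0.15). It also ended without the 3 arrays with the highest Ovgp1 (0.16) and with the replicate block (0.1). The immediate early call ended without control replicates 1, 5 or 6, stage I replicates 1 or 3, or stage II replicate 3 (up to 0.49), and with quantile normalization (0.058).

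**Figure D3:**
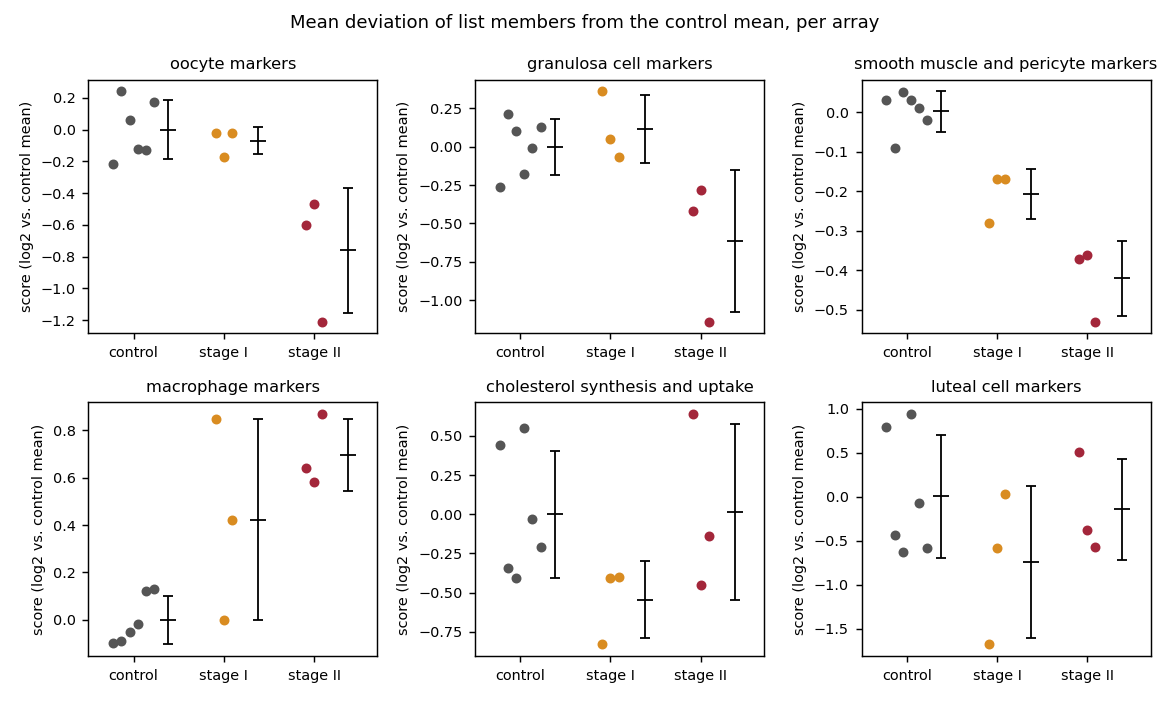
Score of 6 gene lists per array, the mean deviation of the list's members from the control mean on the log2 scale (vertical, a separate range in each panel), in the 3 groups (horizontal), with the group mean and SD as bars. Oocyte and granulosa scores are lowest in stage II replicate 3 (-1.21 and -1.14), and the luteal and cholesterol scores of control replicates 1 and 4 lie above those of the other controls.

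Stage II against control showed increases of up to 340-fold and decreases of up to 10.1-fold among called genes whose groups did not overlap, predicted genes and clone symbols left out. Prl7a2 was 340-fold higher (log2 8.41 ± 0.39 SE, adjusted p = 1.2e-07), Lcn2 264-fold, Fga 232-fold, Defb8 183-fold, Svs5 122-fold, Ly6d 105-fold, Pmaip1 77.4-fold and Tspan8 57.2-fold. The largest decreases among these genes were in Adipoq, the adipocyte hormone adiponectin (log2 -3.34 ± 0.66 SE, adjusted p = 0.0042), Cyp17a1, the steroid 17-hydroxylase of theca cells (-2.68 ± 0.74 SE, adjusted p = 0.023), and Gabrb2, a GABA receptor subunit (-1.93 ± 0.34 SE). Adipoq varied widely among controls, from 6.29 to 9.88, against 4.85 to 6.17 in stage II. Asgr1, a receptor for asialoglycoproteins (-1.78), Cyp2e1, a cytochrome P450 (-1.60), Tnc, the matrix protein tenascin C (-1.59), Sh3bgr (-1.49) and the BMP antagonist Grem1 (-1.48) also fell. The Cyp17a1 levels in stage II were 10.19, 10.26 and 6.06 against 10.79 to 12.18 in controls, and without stage II replicate 3 its log2 change was -1.29, and it was as low as -3.39 without replicate 1 or 2.

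In all, 2302 genes passed limma's threshold, 1074 higher and 1228 lower, and 274 differed by at least 2-fold, 244 of them higher. The split was 986 higher and 1634 lower with quantile normalization, and 982 and 1509 with the array medians centred. Without stage II replicate 3 the count was 1145, with 713 higher and 432 lower. The calls of Tnc, Sh3bgr (adjusted p = 0.057) and Grem1 were lost without that array, that of Grem1 also without stage II replicate 1 (adjusted p up to 0.097), and that of Tnc also without control replicates 1, 4 or 6 (adjusted p up to 0.19).

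Markers of oocytes, granulosa cells and theca cells fell in stage II. All 11 oocyte markers fell, by a median log2 change of -0.76, and 11 were lower adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.48 with an estimated correlation). They include Zp3, a zona pellucida protein (-0.81 ± 0.14 SE), Nlrp14 (-0.93 ± 0.19 SE) and Nlrp5 (-0.90 ± 0.13 SE), both maternal-effect genes, and the oocyte linker histone H1f8 (-0.81 ± 0.16 SE). Of 10 granulosa markers 7 fell and 0 rose (7 adjusted over the list alone, adjusted p = 0.0079, and adjusted p = 0.57 with an estimated correlation). Inhba, a beta subunit of activin and inhibin, had a log2 change of -1.77, and Amhr2, the receptor of anti-Müllerian hormone, had -0.72. The Inhba call ended without stage II replicate 3 (log2 -1.04, adjusted p = 0.062). Nap1l5 and Inhbb also fell, and each call ended without any 1 of several arrays (adjusted p up to 0.24 and 0.15). Of 8 theca and interstitial markers 6 fell and 1 rose (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation). Hhip, which binds hedgehog ligands (-0.63), and Pdgfra, a growth factor receptor (-0.50), were among those that fell. Ptch1 also fell, a call that ended without stage II replicate 1 or 3 (adjusted p up to 0.11).

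Stromal lists also fell in stage II. Of 10 smooth muscle and pericyte markers 7 fell, as many as adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.43 with an estimated correlation), led by the contractile genes Cnn1 (-1.05 ± 0.08 SE), Actg2 (-1.02 ± 0.09 SE), Tagln (-0.78) and Acta2 (-0.66). Of 14 fibroblast and matrix genes 9 fell and 2 rose, the same counts as adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.43 with an estimated correlation). The collagens Col5a1 (-0.63) and Col5a2 (-0.58) fell, while Fn1 rose 8.01-fold (log2 3.00 ± 0.24 SE, adjusted p = 4.5e-06) and Mmp2 rose 1.73-fold. Without the dimmest genes the fibroblast and matrix list did not pass (adjusted p = 0.056).

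Macrophage, interferon, proliferation and p53 lists were higher in stage II. Of 9 macrophage markers 6 rose and 0 fell, also 6 adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.50 with an estimated correlation), with Cd14 at 5.68-fold and Aif1, a calcium-binding protein of macrophages, at 1.80-fold. Of 5 interferon response genes 4 rose, also 4 adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.54 with an estimated correlation), with Usp18 at 2.28-fold and Rsad2, an antiviral gene, at 1.83-fold. Of 17 proliferation genes 3 rose, also 3 adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.69 with an estimated correlation), led by Rrm2 (8.33-fold). Of 8 p53 targets 3 rose, also 3 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.43 with an estimated correlation), Pmaip1, Mdm2 at 2.43-fold and Ccng1 at 1.93-fold. The proliferation call ended without stage II replicate 3 (adjusted p = 0.084) and the interferon call without stage II replicate 1 (0.099), while the Usp18 call ended without stage II replicate 1 or 3 (up to 0.069). Both lists also missed the threshold without control replicates 1 and 4 together (0.051 and 0.073). Calls of the macrophage markers Fcgr1 and C1qa ended without single arrays (adjusted p up to 0.16 and 0.17). So did those of the interferon genes Oas1a and Irf7 (up to 0.063 and 0.14) and the proliferation genes Nusap1 and Mcm6 (up to 0.081 and 0.15).

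Targets of the progesterone receptor known from other settings went both ways in stage II. Of 9 targets in ovulating granulosa cells 3 rose, among them Zbtb16, a zinc finger transcription factor (6.52-fold), and Prkg2, a cGMP-dependent kinase (3.36-fold), and 1 fell, the co-regulator Cited2 (log2 -0.36), also 3 and 1 adjusted over the list alone. Of 15 targets in uterus and mammary gland 4 rose and 3 fell, or 4 and 4 adjusted over the list alone. Lrp2, the endocytic receptor megalin (5.50-fold), Hand2, a transcription factor of the uterine stroma (4.86-fold), and Tsc22d3, a glucocorticoid-responsive gene (1.59-fold), rose, and Il13ra2, an interleukin 13 receptor (log2 -0.61), fell. Neither list passed its own test (adjusted p = 0.21 and 0.24). The Cited2 call ended without control replicates 1, 2, 3, 5 or 6, stage I replicate 3, or stage II replicates 1 or 3 (adjusted p up to 0.19).

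Single members of other lists differed strongly in stage II while their lists did not pass. Krt8, an epithelial keratin, rose 12-fold and Bnc1, a zinc finger gene of mesothelium, fell (log2 -0.80) among 7 surface epithelium markers. Ccnd1 rose 20.6-fold and Rnf43, a ubiquitin ligase acting on Wnt receptors, fell (-0.59) among 10 Wnt targets. Ndrg1 rose 8.79-fold among 14 hypoxia and glycolysis genes, of which 3 rose and 1 fell. Parm1 rose 8.30-fold among 7 luteal markers, of which 1 rose and 1 fell. The tight junction gene Cldn11 rose 6.32-fold among 8 Sertoli cell markers, of which 3 rose and 1 fell. Fabp4, a fatty acid binding protein, rose 5.54-fold among 7 adipocyte markers, of which 2 fell, Adipoq among them. Fos rose 2.62-fold and Jun fell (-0.76) among 9 immediate early genes. In camera the adjusted p of these 7 lists lay between 0.3 for the Sertoli markers and 1 for the luteal markers, and without the dimmest genes the Sertoli markers passed (0.038). Cyp17a1 was the 1 of 5 steroid synthesis genes that passed (list adjusted p = 0.55). Singly, 0 of 12 cholesterol synthesis genes, 0 of 12 lymphocyte markers and 0 of 3 red blood cell markers passed in stage II (list adjusted p = 0.91, 0.54 and 0.74). Of 12 endothelial markers Flt1 (1.76-fold) and Robo4 (1.30-fold) rose, also 2 adjusted over the list alone, and the list did not pass (median 0.21, adjusted p = 0.061). It passed without control replicates 1 and 4 together (median 0.33, adjusted p = 0.0013, with high endothelial scores of 0.24 and 0.21 in these controls), without the 3 arrays with the highest Ovgp1 (0.047), and without control replicate 1, control replicate 4 or stage II replicate 2 alone (as low as 0.017). The calls of Bnc1, Jun and Robo4 ended without stage II replicate 1 or 3 (adjusted p up to 0.093, 0.081 and 0.094).

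The oviduct and ciliated epithelium list passed in none of the 4 comparisons. Ovgp1, an oviduct secretory glycoprotein, was at 12.7 in control replicate 5, 11.77 in stage I replicate 2 and 11.58 in stage II replicate 2, and its group means differed by less than their spread (7.87 ± 2.54 in controls, n = 6, against 9.09 ± 2.88 in stage II, n = 3). Cldn3, a claudin, was the 1 member of 10 that rose in stage II (2.67-fold, adjusted p = 7e-05), also 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.83). In stage I against control 8 members were above 0 and the list did not pass in camera (adjusted p = 0.16). It passed there without control replicate 5, stage I replicate 1 or stage I replicate 3 (as low as 0.0069). With the replicate number as a block it also passed (0.00079).

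Stage II against stage I tested the difference between the stages itself. Among called genes whose groups did not overlap, predicted genes and clone symbols left out, the largest increases were in Prl7a2 (14-fold, log2 3.81 ± 0.45 SE, adjusted p = 0.00042), the fibrinogen chains Fgb (13.4-fold) and Fgg (10.1-fold), Ly6d (11.9-fold), the glucuronosyltransferase Ugt2b34 (11.4-fold), Lifr, the receptor of leukemia inhibitory factor (9.79-fold), Defb8 (8.97-fold) and Slc16a6, a transporter of the monocarboxylate family (8.52-fold). Among the decreases, Cyp17a1 fell by 3.42 on the log2 scale (SE 0.85, adjusted p = 0.023), Adipoq by 3.16, Gabrb2 by 1.90, Inhba by 1.89, Cyp2e1 by 1.5, Mtcl1 by 1.49, the sulfotransferase Chst8 by 1.31 and Tmem45a by 1.29. Leaving out single arrays ended the calls of Cyp17a1 (any stage I array, adjusted p up to 0.067), Adipoq (stage I replicates 2 or 3, stage II replicates 1 or 3, up to 0.083), Inhba (any stage I array, stage II replicates 1 or 3, up to 0.089), Cyp2e1 (stage I replicate 3, 0.05), Mtcl1 (stage I replicate 3 or stage II replicate 3, up to 0.067) and Chst8 (control replicate 5, any stage I array, stage II replicates 1 or 3, up to 0.16). Without stage II replicate 3 the log2 change of Cyp17a1 was -2.03, of Inhba -1.16 and of Ugt2b34 2.55, and without stage II replicate 1 or 2 Cyp17a1 was as low as -4.13. Without stage I replicate 1 it was 4.55 for Prl7a2, 4.41 for Fgb, 4.18 for Ly6d and 4.02 for Defb8, and without stage II replicate 1 it was 3.95 for Fgg.

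There were 1370 genes past the threshold, 716 higher and 654 lower in stage II, or 684 and 936 after quantile normalization, and 206 differed by at least 2-fold. The count was 632 without stage I replicate 2, 605 without stage I replicate 3, 633 without stage II replicate 3, 393 in a fit of these groups alone, 2308 with array weights and 544 without the 3 arrays with the highest Ovgp1.

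Of 11 oocyte markers 10 fell between the stages, 11 adjusted over the list alone (median log2 -0.69, adjusted p = 1.4e-06, and adjusted p = 0.48 with an estimated correlation), such as Zp3 (-0.76 ± 0.17 SE). Nlrp14, Tcl1 and Bmp15 also fell, but their calls each ended without single arrays (adjusted p up to 0.077, 0.09 and 0.12). Of 10 granulosa markers 5 fell, 8 adjusted over the list alone (median -0.81, adjusted p = 0.0011, and adjusted p = 0.49 with an estimated correlation), Amhr2 among them (-0.79), whose call ended without stage II replicate 3 (adjusted p = 0.057). The Inhbb and Inha calls also ended without single arrays (adjusted p up to 0.089 and 0.052). Theca markers had 4 fallen of 8, 5 adjusted over the list alone (adjusted p = 0.0061, and adjusted p = 0.44 with an estimated correlation), with Hhip at -0.58. Fibroblast and matrix genes had 6 fallen and 2 risen of 14, 8 and 2 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.43 with an estimated correlation), with Col6a2 at -0.56, and the list did not pass without the dimmest genes (0.053). Smooth muscle markers had 4 fallen of 10, with 6 lower and 3 higher adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.49 with an estimated correlation), a call that ended without control replicate 1 or stage II replicate 3 (up to 0.064), without control replicates 1 and 4 together (0.067) and without the dimmest genes (0.066).

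Cholesterol synthesis genes were higher in stage II than in stage I, with a median of 0.50 and 10 of 12 above 0. Idi1, an isomerase of that pathway, was the 1 member that rose (2.62-fold, adjusted p = 0.017), also 1 adjusted over the list alone (adjusted p = 0.020, and adjusted p = 0.69 with an estimated correlation). The list's call ended without stage I replicate 1 or stage II replicate 1 (adjusted p up to 0.32), and the Idi1 call also without stage II replicate 3 (up to 0.071). Endothelial markers had a median of 0.27 with 2 risen of 12, 3 adjusted over the list alone (adjusted p = 0.0071, and adjusted p = 0.64 with an estimated correlation), Flt1 (1.94-fold) among them. Proliferation genes had 2 risen of 17, Rrm2 (4.34-fold) among them, also 2 adjusted over the list alone (adjusted p = 0.020, and adjusted p = 0.69 with an estimated correlation), and without stage II replicate 3 the list did not pass (0.16). Of 8 p53 targets Pmaip1 (5.23-fold), Mdm2 (2-fold) and Ccng1 (1.70-fold) rose, also 3 adjusted over the list alone (adjusted p = 0.020, and adjusted p = 0.44 with an estimated correlation). Without stage I replicate 1 the log2 change of Pmaip1 was 3.02 against 2.39 with it. Hspa1b, a heat shock protein, was lower in stage II than in stage I (log2 -1.26, adjusted p = 0.012). Its stage II levels (9.61 to 9.74) lay within those of controls (9.50 to 9.97), while the stage I arrays were at 10.20, 10.90 and 11.68.

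All 21 genes called in stage I were also called higher in stage II, where independent lists of these sizes would share 2.06. In the direct test 17 of them passed as higher in stage II than in stage I, and the median difference of the 21 was 2.09 on the log2 scale. The simulated unchanged groups against the same controls shared a median of 0 calls. With the controls split into 3 and 3, the overlap had a median of 13 over 20 splits (11 to 18). Across genes, which are not independent replicates, the log2 fold changes of the stages had a Pearson r of 0.675 and a covariance of 0.0745. In the simulation the median r was 0.366, the highest 0.792 and the median covariance 0.00685, and in the split controls the median r was 0.605 (0.398 to 0.694) and the median covariance 0.0701.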

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

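The 2 tests of the marker pattern in this part were chosen only after the result was seen, and the counts over other splits of the arrays were planned before it.

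Marker lists that differed between the stages were singled out by camera's direct test of stage II against stage I. Their median log2 differences were -0.81 for granulosa cell markers, -0.69 for oocyte markers, -0.37 for theca and interstitial markers, -0.36 for fibroblast and matrix genes and -0.27 for smooth muscle and pericyte markers. They were 0.50 for cholesterol synthesis genes, 0.38 for p53 targets, 0.27 for endothelial markers and 0.19 for proliferation genes. Without 1 array some moved by over 1.5 times, to 0.24 for cholesterol synthesis genes without stage II replicate 1 (adjusted p = 0.32), 0.19 for p53 targets without stage I replicate 1 (0.044) and 0.11 for proliferation genes without stage II replicate 3 (0.16). With an estimated correlation 0 of the 96 list tests passed. Under quantile normalization the granulosa, theca, oocyte, fibroblast and smooth muscle lists still passed in stage II against control, with medians of -0.67, -0.48, -0.80, -0.45 and -0.44 (adjusted p up to 0.043). The deposited values had been brought to nearly 1 distribution before this, and that first step could not be undone.

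The lower follicle and stromal markers in stage II were weighed against 2 technical explanations. Added tissue that dilutes every other cell type alike would lower endothelial, macrophage and luteal markers too. Median stage II changes were 0.21 (SD 0.25 over members) for endothelial and 0.50 (SD 0.71) for macrophage against -0.76 (SD 0.13) for oocyte markers. The luteal -0.29 (SD 1.69) decides nothing. Added tissue that holds its own vessels and macrophages could raise the endothelial and macrophage lists and still dilute the others. These values therefore cannot decide on dilution by such tissue. Without stage II replicate 3 the medians shrank, from -0.76 to -0.53 for oocyte, -0.64 to -0.44 for granulosa, -0.44 to -0.28 for theca, -0.43 to -0.35 for fibroblast and -0.41 to -0.35 for smooth muscle markers, with at least 63.1 percent of each left and adjusted p up to 0.038, so that array enlarged the pattern but is not its only source. Dilution by added tissue, a smaller number of follicles and stromal cells, or lower expression within them may underlie the pattern, which array values cannot separate. A smaller number of follicles stays a hypothesis that follicle counts in sections, not analysed here, would test.

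Other splits of the arrays gave fewer genes than the real groups. The genotype comparison called 740 genes, and the highest of the other splits among 100 called 107. Stage I against control called 21, and the highest of the other splits among 84 called 7. Stage II against control called 2302, and the highest of the other splits among 84 called 22. In each of these, 1 split, the real one, reached the count, which is 1 in 100, 1 in 84 and 1 in 84 splits. Splits that mix the real groups also carry the group differences in their spread, which lowers their counts. The splits do not bear on batch or litter, which the sources used here do not give. For stage II against stage I, with 1370 genes against 6 in the highest other split, the 10 splits are too few for a share under 0.05.

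Single control arrays stood far from the other 5 in 7 of 151 sets of control values tested, where chance gives about 1 in 20. The oviduct list score was 0.96 in control replicate 5. In control replicate 1, Cd2 was at 4.18 and Fkbp4 at 9.71. In control replicate 4, Cldn11 was at 5.58 and Robo4 at 7.53. Gzmb was at 4.76 in control replicate 2, and Tnfsf11 was at 6.5 in control replicate 6.

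Among the 1702 probe sets with no gene symbol or several, which the comparisons did not use, 248 passed the threshold in stage II against control, 125 higher and 123 lower.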

How the results depend on the processing

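Leaving out control replicates 1 and 4, and leaving out the 3 arrays with the highest Ovgp1, were chosen only after the data were seen, and the other alternatives were planned. Of the counts, stage I moved from 21 to 32 with every probe set, 13 without control replicates 1 and 4, and 11 without the high-Ovgp1 arrays. The genotype count moved from 740 to 42 with 2 groups fitted alone, 1321 with array weights and 138 at 2-fold. Stage II against control moved from 2302 to 274 at 2-fold. Stage II against stage I moved from 1370 to 393 with these groups alone, 2308 with array weights, 206 at 2-fold and 544 without the high-Ovgp1 arrays. The overlap of the stages moved from 21 to 13 with the controls split. A floor of 2-fold can only remove genes, and leaving out arrays leaves fewer samples. Testing every probe set means 16376 rows in place of 10949. A fit with 1 mean for both stages puts their difference, called in 1370 genes, into the spread. How much these account for, and the cause of the other moves, was not tested. With each array left out in turn the counts ran from 531 to 882 for the genotype, 15 to 28 for stage I, 1145 to 2432 for stage II and 605 to 1610 for stage II against stage I. The moves beyond 1.5 times were 1145 for stage II without stage II replicate 3, and for stage II against stage I 632 without stage I replicate 2, 605 without stage I replicate 3 and 633 without stage II replicate 3. Stage II against control lay within 1.5 times its count under the other scalings, filters and fits except the replicate block.

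Replicate numbers recur across groups, but the labels do not pair the samples, and deviations of same-numbered arrays correlated at -0.13 to 0.2. With the number as a block the counts were 219, 6, 1090 and 602 in the order genotype, stage I, stage II, and stage II against stage I. Numbers 4, 5 and 6 occur only among controls, so with the block these controls add nothing to the comparisons. The block also leaves fewer residual degrees of freedom. How much of the moves comes from this was not tested.

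Of the 96 list tests, of which 31 passed, 31 missed the threshold with an estimated correlation, 11 with some array left out, 3 with quantile normalization, 5 without the dimmest genes, 3 with the block, 7 without control replicates 1 and 4 and 2 without the high-Ovgp1 arrays. Others came to pass, 14 with some array left out, 3 without the dimmest genes, 4 with the block, 6 without control replicates 1 and 4 and 5 without the high-Ovgp1 arrays. Without the dimmest genes 84 tests kept their result, so fewer than 96 were made there. The naming rule took 266 results for genes, not all given in the text, of which 202 passed. Of these, 56 missed the threshold with some array left out and 73 with the block. With the mean of probe sets 4 missed it, with quantile normalization 1 did, and 0 reversed. Signal over background could not be assessed from the values.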

Other observations

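The tests on chromosome 4 and on genes known from other organs in this part were all chosen only after the results they concern were seen, as were the gene lists of liver, placenta and the male tract and the genes named here.

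Genes of chromosome 4 (RefSeq assembly GRCm38.p6) were lower in stage II. Of 626 tested, 179 were called lower and 30 higher, so 28.6 percent were lower against 10.2 percent of 10275 genes on other chromosomes. The median shift of its genes above the median level of expression, relative to all genes, was -0.12, -0.14 and -0.25 on the log2 scale in stage II replicates 1, 2 and 3, against an SD of 0.004 in controls and a largest shift of 0.04 in size among the 6 controls over all 20 chromosomes. The chromosome's adjusted p in camera was 2.7e-05, and adjusted p = 0.15 with an estimated correlation. Among stage I arrays replicate 1 had -0.04, with 9 of 10 blocks of genes along the chromosome lower and 64.2 percent of its genes below 0, so a smaller shift of the same kind in that array stays open. Chromosome 14 had -0.29 in stage II replicate 3 alone, against 0 and -0.01 in the other stage II arrays, and chromosome 19 had 0.11 there. No measured member of the oocyte, granulosa, theca, fibroblast or smooth muscle list lies on chromosome 4.

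A segment carried with the PgrBLsL allele would also show in stage I, where the mean shift was -0.016. Loss of follicle cells predicted a shift of 0.029 (SE 0.014) from the granulosa score over the other 9 arrays. Their scores ran from -0.26 to 0.36, and the line was extended to stage II scores of -0.42, -0.28 and -1.14. The highest score was that of stage I replicate 1, which may carry the shift itself. This prediction therefore cannot decide on loss of follicle cells. Of 10000 lists of genes from other chromosomes matched on level and number, 0 were as low, and the lowest was -0.048. These lists mix chromosomes, so they bear on level and number of genes and not on shifts of a whole chromosome. Chromosome 14, through stage II replicate 3 alone, had a stage II mean of -0.10, also below that value. In 30 of 30 cases, 10 blocks of genes along the chromosome in 3 stage II arrays, the block was lower, as a change over the whole chromosome requires. Loss of 1 copy in part of the cells may therefore be a hypothesis for stage II, and DNA copy number was not analysed here.

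Some genes known mainly from liver, placenta or the male tract were among the higher calls, Fga, Svs5 and Prl7a2 in both stages and Apoa1, Apoh, Fgb, Fgg and Svs6 in stage II, and 3 sources of foreign tissue were weighed. For liver RNA, 18 abundant liver genes had a median stage II change of 0.18 (median absolute deviation 0.33) with 7 higher. Albumin (Alb, 0.04) and Apoa2 (0.12) did not pass, while Apoa1 (3.21), Apoh (4.27), Fga (7.86), Fgb (5.68) and Fgg (4.27) did. For placenta or male tract, 16 genes had a median of 0 (median absolute deviation 0.09) with 3 higher, Svs6 among them (5.78), while Svs2 (-0.12) and Svs4 (0.01) did not pass. For oviduct, the array with the highest Ovgp1 in each group differed from the others of its group by -0.27 in the median of the 10 such genes called higher (median absolute deviation 0.26), against a median stage II change of 4.97, and control replicate 5, with Ovgp1 at 12.7, had Fga at 3.19 and Prl7a2 at 3.21, so expression within the ovary or its tumor may remain as a hypothesis, untested here.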
